A study of Mus musculus with 48 samples.

How the data were processed

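RNA from mouse cortical neuron cultures was measured on 48 Illumina MouseWG-6 arrays, 6 on each of 8 chips, at positions A to F. Per the labels, CD-1 cultures were kept for 7 days, pre-incubated with a compound for 1 h, exposed to NMDA for 1 h in a hypotonic salt solution and left to recover for 16 h. Doses are not given in the sources used here, nor is the assay behind the protection ratio.

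The deposited signals are average bead intensity values per probe on a linear scale that the authors exported with BeadStudio, without background subtraction or scaling between arrays; the version and settings of BeadStudio are not given. Per the file headers each signal is followed by its detection p-value, and the deposited detection p-values step by the share of 1 in 1603 negative control beads. The deposited series matrix holds the intensity of each probe less 1 constant per array (32.3 to 111), and 8 of its values differ from that constant by more than 0.1. Every column was matched to a sample (0 columns without one).

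The signals of 46632 probes were corrected for background with the normexp model of limma from the detection p-values (function nec, offset 16), quantile normalized and put on the log2 scale. A probe was tested when its detection p was under 0.01 on at least 6 of the 48 arrays. This kept 17815 probes, of which 13937 carry a symbol of 9869 genes and 10051 were detected on all arrays. Symbols come from an old annotation of the arrays: 29976 probes carry 1 symbol, 10 carry several and 16646 carry none, and 0 were updated. Arrays give no counts, so their number limits the precision. The median signal ranged from 36.1 to 124 between arrays, the share of probes with a detection p under 0.01 from 26.3% to 39.0%, and the median correlation of an array with the others from 0.906 (clofibric acid) to 0.966.

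Samples were grouped by the class, mechanism and treatment that the labels give. Differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with tables read by data.table (version 1.17.8), and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05 over the probes tested. All p are two-sided. The comparisons were the protective class against the non-protective class (14 against 16 arrays); protective compounds, non-protective compounds and controls against each other in 1 fit (14, 6 and 10); the 4 compounds labelled NMDAR antagonist against the controls and against the 10 other protective compounds; vehicle against mock controls (5 against 5); a slope on the log2 protection ratio over 36 compounds, with the 2 repeat arrays averaged; and a moderated F test over mechanisms with at least 3 compounds. These comparisons, the groups and the gene lists were chosen before the data were examined.

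The 34 lists of known genes were tested with limma's camera with a preset correlation of 0.01 between genes, with 1 probe per gene and at least 3 measured members, adjusted over the lists within a comparison. The alternatives were camera with an estimated correlation and fry, whose p tests whether the genes of a list move, on balance, in 1 direction without comparing them with other genes. With an estimated correlation 0 lists passed in any comparison. List tests with chip, chip set, position or solvent as a term were run by camera with the preset correlation only. Counts of list members were adjusted over all probes and also over the list alone. Within-chip values are differences of group means on each chip with arrays of both groups, averaged over the list.

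Genes are named by a fixed rule. In each comparison these are the 10 largest rises and 10 largest falls among genes past the threshold, with the probe of highest mean for each gene. Where fewer than 5 passed, they are the 5 with the smallest p, named as not passing. For a list, they are up to 4 members with the smallest p, and for a single compound the members of its list and its 3 largest rises and 3 largest falls at least 1 log2 unit from the control mean and outside the controls. Some further members of lists, and the 22 lists that did not pass in the contrast of antagonists and controls, are named beyond the rule and were chosen after their values were seen. A gene undetected on all arrays of a group is given as a bound, with its values raised to the lowest value of a detected probe on each array.

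Each single compound was set against the mean of the 10 controls, and each control against the other 9. Where chip means were subtracted, they were taken over all arrays of the chip, the compound's own included, which removes part of its difference. Each list was also set against 10000 random lists of like expression. Scores of a list on an array are means of its centred log2 values, and their correlations with the ratio were tested with 100000 permutations in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

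The fits were tested on simulated data with changes of 0.5, 1 and 2 log2 units in 67, 67 and 66 of 17815 probes. The share recovered was 55.2%, 95.5% and 100% for the class contrast with 9 false calls, 29.9%, 86.6% and 100% for protective against non-protective compounds with 13, and 46.3%, 86.6% and 98.5% for protective compounds against controls with 5. It was 25.4%, 94% and 97% for non-protective compounds against controls with 12, 58.2%, 94% and 98.5% for the slope with 7, and 1.49%, 56.7% and 90.9% for vehicle against mock controls with 5. For NMDAR antagonists it was 19.4%, 64.2% and 97% against controls with 9, and 16.4%, 58.2% and 97% against other protective compounds with 4. The list that was moved was called in every simulated comparison, with 0 other lists. The simulated probes varied independently of each other, without effects of chip or position. The false calls of probes and lists therefore do not measure those to be expected on the real arrays.

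Alternatives were no background correction, median scaling, the series matrix values, no filter or detection on all arrays, trend and robust variance, array weights, chip or solvent as a term, all 48 arrays in the fit, leaving out each array, another scale or set of samples for the slope, a replicate block for the controls, and for single compounds other controls, probes and chip centring. After the data were seen, chips 1 to 5 against 6 to 8 as a block, position as a covariate, subsets of chips and the removal of arrays that stood apart, of the 4 antagonists or, for gene lists, of 4-PPBP were added. Each count, except those of the slope, was also set against 100 splits of the same samples. Microarray scans were not used here.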

Results

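Cultured mouse cortical neurons can be killed by overstimulating their NMDA receptors, the glutamate-gated channels that let calcium into the cell. The 48 arrays of the series measured RNA in such cultures from CD-1 mice, an outbred stock, after 7 days in culture, a pre-incubation of 1 h with a compound, 1 h of NMDA and 16 h of recovery. Of the 36 compounds, the labels put 14 in a protective class with protection ratios of 1.40 to 2.76 and 6 in a non-protective class with ratios of 0.61 to 0.98, which the 10 mock and vehicle controls join at a ratio of 1.00. The remaining 18 arrays, with ratios of 1.02 to 1.38, belong to neither class. Every culture received NMDA, so the values compare one exposed culture with another and not exposed with unexposed neurons. The labels do not say whether the samples came from separate cultures, and each compound has 1 array, except Z-VAD-FMK and MitoPBN with a repeat array each. The labels call the compound of the second MitoPBN array MitoPBN2 and do not say whether it is the same one; its title numbers it as the repeat, and it was averaged as such in the slope.

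Neuronal and synaptic transcripts were far more abundant in cultures given an NMDA receptor antagonist than in controls. Synaptophysin (Syp), a membrane protein of synaptic vesicles, rose 5.42-fold (log2 2.44, SE 0.316, adjusted p = 7.33e-05; mean log2 intensity 10.98 ± 0.272 SD, n = 4, against 8.54 ± 0.67 SD, n = 10). Beta-synuclein (Sncb), an abundant protein of nerve terminals, rose 6.58-fold (log2 2.72, SE 0.475, adjusted p = 0.00042). The largest rise among named genes was that of Stum, a transmembrane protein gene, at 7.24-fold (log2 2.86, SE 0.461, adjusted p = 0.000251), and 7 of the 10 controls had detectable Stum. The cell cycle kinase Cdk1 fell by 1.29 on the log2 scale (SE 0.347, adjusted p = 0.0107, n = 4 against 10). The 4 antagonists by label are MK-801 and memantine, which block the open channel, ifenprodil, which binds receptors with the GluN2B subunit, and riluzole, better known for reducing glutamate release.

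In this contrast limma called 3445 of 17815 probes, 1996 higher and 1449 lower, with a median absolute log2 difference of 0.66 among them. They covered 2157 genes, 1253 higher and 904 lower. With median scaling in place of quantile normalization the count was 3143, of which 2142 were higher and 1001 lower. The other large rises were those of Lrfn5 (log2 2.68), a synaptic adhesion protein, Myh8 (2.63), Camkv (2.54), Caln1 (2.47), the cell adhesion gene Chl1 (2.47), the neuropeptide gene Cck (2.46) and Lin7b (2.44). The large falls were those of 6820408C15Rik (-1.49), Rln1 (-1.42), the actin-binding genes Palld (-1.37) and Cnn2 (-1.30), the kinetochore gene Spc25 (-1.29), Rasl11a (-1.28), Tk1 (-1.23) and Shcbp1 (-1.23). Plekha7 was undetected on all 4 antagonist arrays and was at least 1.53-fold lower. With chip as a block 11 of the 20 genes in this and the preceding paragraph passed, the 10 rises and Spc25, and 9, Cdk1 and the other falls, did not (adjusted p up to 0.376); with position as a covariate 9 of the 20 passed.

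Of the 19 general neuron markers, 18 were called higher and none lower, with a median log2 difference of 1.45 (camera adjusted p = 4.33e-14, but adjusted p = 0.185 with an estimated correlation). Syn1 (2.13), Stmn2 (1.87), Rbfox3 (1.80) and Syt1 (1.79) were among them. Of 24 synapse genes 22 were called higher, 23 when adjusted over the list alone (median 1.17, adjusted p = 1.53e-16, and 0.185 with an estimated correlation), including the vesicle genes Sv2b (2.23) and Sv2a (1.51). Excitatory neuron markers had 8 of 10 genes called higher (median 0.99, adjusted p = 8.37e-06, and 0.185 with an estimated correlation). The transcription factor genes Neurod2 (2.38) and Tbr1 (1.57) and the vesicular glutamate transporter gene Slc17a6 (2.07) were in that list, as was Slc17a7, detected on 3 of 4 antagonist arrays and 1 of 10 controls. Inhibitory neuron markers had 5 of 9 called higher, 7 over the list alone (median 0.97, adjusted p = 0.00212, and 0.185 with an estimated correlation), with the GABA genes Slc32a1 (1.40), Gad2 (1.28) and Gad1 (0.97). Glutamate receptor genes had 8 of 13 called higher, 10 over the list alone (median 0.80, adjusted p = 8.37e-06, and 0.235 with an estimated correlation), among them Grm7 (1.92, detected on 4 of 10 controls), Gria1 (1.40) and the NMDA receptor subunit Grin2b (1.11).

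Cell division genes moved the other way: 14 of 18 were called lower and none higher, 16 over the list alone (median -1.02, adjusted p = 2.05e-06, and 0.333 with an estimated correlation), with Aurka (-1.16) and Top2a (-1.02) beside Cdk1. Cholesterol synthesis and SREBP2 target genes had 7 of 18 called higher (median 0.37, adjusted p = 0.00108, and 0.333 with an estimated correlation). These included the pathway enzymes Mvd (1.02), Fdps (0.88) and Dhcr7 (0.80). Calcium and potassium homeostasis genes had 8 of 18 called higher and 2 lower, 9 and 2 over the list alone (median 0.39, adjusted p = 0.0136, and 0.188 with an estimated correlation). The calcium release channel Ryr2 (1.19), the kinase Camk4 (1.15) and the calcineurin subunit Ppp3cb (1.04) were higher, and the calpain inhibitor Cast (-0.72) was lower. Inflammatory and NF-kB target genes had 4 of 16 called lower, 5 over the list alone (median -0.42, adjusted p = 0.00222, and 0.297 with an estimated correlation), among them Csf1 (-0.93) and the adhesion molecules Vcam1 (-0.79) and Icam1 (-0.59). Interferon-stimulated genes had 2 called lower (median -0.43, adjusted p = 0.00073, and 0.297 with an estimated correlation), Gbp3 (-0.69) and Ifit3 (-0.66). Folate cycle and nucleotide synthesis genes had 4 of 16 called lower and 1 higher, 6 and 1 over the list alone (median -0.36, adjusted p = 0.0198, and 0.297 with an estimated correlation), with Tyms at -1.08, Rrm2 at -1.07 and Impdh1 at 1.36. Proteasome genes had 4 of 36 called lower, 2 over the list alone (median -0.19, adjusted p = 0.0136, and 0.235 with an estimated correlation).

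The other 22 of the 34 lists had adjusted p of 0.0905 to 0.758 in this contrast. Their median log2 differences were -0.39 for immediate early and activity-regulated genes, -0.46 for activity-regulated inhibitor of death genes, -0.17 for astrocyte and radial glia markers, -0.17 for oligodendrocyte lineage markers, -0.34 for microglia markers and -0.61 for endothelial, mural and meningeal cell markers. For stress and death programmes they were -0.29 for p53 target genes, -0.05 for apoptosis regulators, -0.07 for integrated stress response genes, -0.10 for endoplasmic reticulum chaperone genes, -0.16 for heat shock genes, -0.11 for Nrf2 target genes and -0.03 for metallothionein genes. For hormone and signalling targets they were -0.22 for glucocorticoid, 0.37 for thyroid hormone, -0.16 for cAMP-CREB, -0.32 for PPARalpha and -0.40 for aryl hydrocarbon receptor target genes. For metabolism they were -0.11 for hypoxia and glycolysis genes, 0.06 for lysosome and autophagy genes, -0.03 for oxidative phosphorylation genes (0.02 with median scaling) and 0.05 for cytosolic ribosomal protein genes. Single members of these lists nevertheless passed: the pro-apoptotic gene Hrk, detected on 4 of 4 antagonist arrays and 1 of 10 controls, had a higher mean (adjusted p = 0.000176), Egr3 rose by 1.18, the neuronal glucose transporter Slc2a3 rose by 1.02, and the progenitor marker Nes was lower (-0.80).

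On the 3 chips that hold antagonists and controls, the neuron markers were higher on 3 of 3 (mean log2 0.89 to 1.52 per chip) and the synapse genes on 3 of 3 (0.92 to 1.38). Cell division genes were lower on 3 of 3 chips (-0.80 to -0.49), SREBP2 target genes higher on 3 of 3 (0.24 to 0.67) and interferon-stimulated genes lower on 2 of 3 (-0.65 to 0.04). Fitting chip as a block gave an adjusted p of 3.68e-12 for neuron markers, 0.00249 for cell division genes and 5.84e-05 for SREBP2 target genes. These p rest on the preset correlation only. Without MK-801 the count was 1665 and without ifenprodil 1782, and with position on the chip as a covariate it was 1371.

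**Figure D1:**
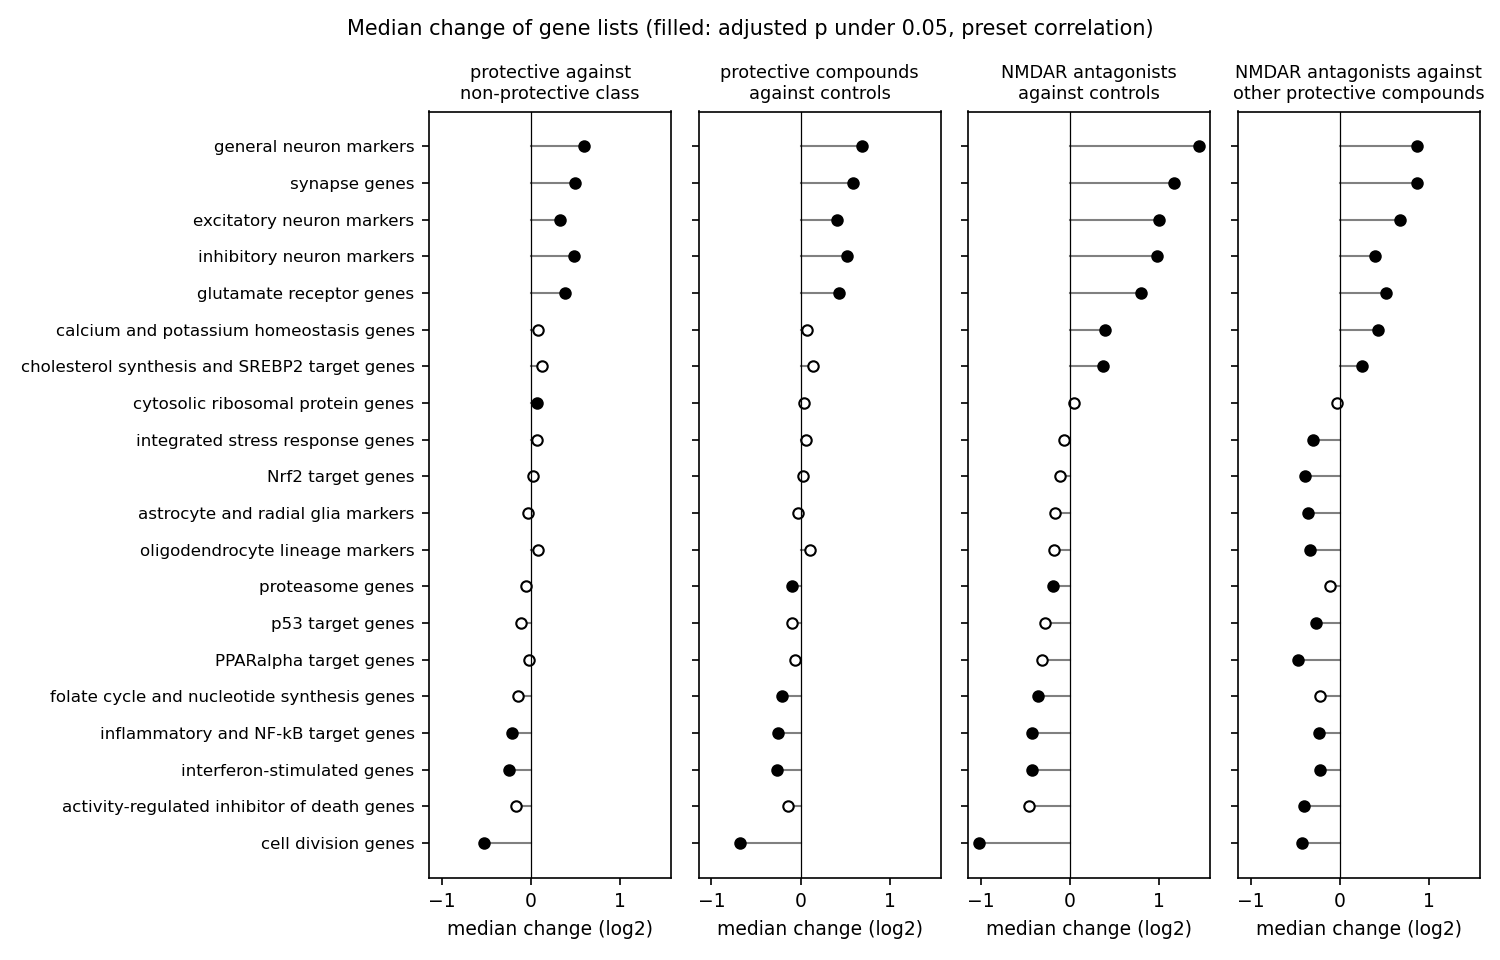
Median log2 difference of the genes of each list in 4 comparisons, with filled points where the camera adjusted p with the preset correlation was under 0.05. General neuron markers had medians of 1.45 for NMDA receptor antagonists against controls and 0.60 for the protective against the non-protective class.

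The antagonist arrays also stood apart from those of the 10 other protective compounds. Sv2b, a synaptic vesicle protein gene, was 4.05-fold higher (log2 2.02, SE 0.388, adjusted p = 0.00445, n = 4 against 10). The vesicular glutamate transporter gene Slc17a6 was 3.49-fold higher (log2 1.80, SE 0.355, adjusted p = 0.00522). The ciliary gene Evc fell by 0.80 on the log2 scale (SE 0.145, adjusted p = 0.00322), and Ezh2, which encodes a histone methyltransferase of dividing precursors, fell by 0.74 (SE 0.182, adjusted p = 0.017). limma called 1024 probes, 779 higher and 245 lower, in 650 genes. Of 100 splits of these arrays, the real one included, 6 called as many probes, so chance cannot be excluded for this count. Stum (log2 2.35), Myh8 (2.23), Lrfn5 (2.16), Cck (2.11), Sertm1 (2.09), Chl1 (1.94), Camkv (1.84) and Lin7b (1.78) completed the largest rises. The largest falls were those of Cldn12 (-0.99), Plscr4 (-0.92), Adhfe1 (-0.76), Gulp1 (-0.74), Nudt7 (-0.73), Golim4 (-0.72) and Mpp5 (-0.72), and Prss23, undetected on the 4 antagonist arrays, was at least 1.28-fold lower. Sertm1 was detected on 2 of the 10 other protective arrays. Of these 20 genes 15 passed with chip as a block, Sv2b, Slc17a6 and Evc among them, and 5 did not, Ezh2 among them.

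Against the other protective compounds, neuron markers had 10 of 19 called higher, 17 over the list alone (median 0.87, adjusted p = 2.19e-14, and 0.121 with an estimated correlation). Synapse genes had 12 of 24 called higher, 20 over the list alone (median 0.87, adjusted p = 2.37e-16, and 0.121 with an estimated correlation). Excitatory markers (median 0.68), glutamate receptor genes (0.52), calcium and potassium homeostasis genes (0.43), inhibitory markers (0.40) and SREBP2 target genes (0.26) were also higher, with adjusted p of 2.3e-06 to 0.00262 and, with an estimated correlation, 0.121 to 0.234. Slc17a7, undetected on the 10 other protective arrays, was at least 1.44-fold higher. PPARalpha target genes were lower (median -0.46, adjusted p = 0.0132, and 0.168 with an estimated correlation), with 2 called lower and 1 higher, 5 and 1 over the list alone. The fatty acid oxidation genes Acadm (-0.58) and Acadvl (-0.50) were the called falls and the fatty acid carrier Fabp3 (0.95) the rise. Nrf2 target genes, the antioxidant programme, had 2 called lower, 4 over the list alone, Gsta4 (-0.40) and Abcc4 (-0.38) being the called pair (median -0.38, adjusted p = 0.0034, and 0.234 with an estimated correlation). Activity-regulated inhibitor of death genes were lower (median -0.40, adjusted p = 0.0195, and 0.121 with an estimated correlation), with Gadd45g (-0.64) called.

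Cell division genes (median -0.42), astrocyte markers (-0.36), oligodendrocyte markers (-0.33), integrated stress response genes (-0.30), p53 target genes (-0.26), inflammatory genes (-0.23) and interferon-stimulated genes (-0.22) were lower too, with adjusted p of 0.0108 to 0.0388 and, with an estimated correlation, 0.165 to 0.529. Both chips that hold the 2 kinds of compound had higher neuron markers with the antagonists (0.65 and 0.97) and lower Nrf2 targets (-0.42 and -0.41), while cell division genes were lower on 1 of them and higher on the other (-0.67 and 0.41). The adjusted p with chip as a block was 2.37e-10 for neuron markers, 0.283 for cell division genes and 0.0705 for p53 targets, with the preset correlation only. Without MK-801 the count was 110 and without ifenprodil 195.

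The protective class as labelled includes the 4 antagonists, and its mean of neuronal genes was higher than that of the non-protective class, by less. Without the antagonists limma called 0 probes, with 10 against 16 arrays, and none of the 20 genes named here passed (adjusted p of 0.207 to 0.425). The neuron marker score averaged 0.902 on the 4 antagonist arrays and -0.0552 on the other 10 protective arrays, of which 5 lay below 0. Sncb rose 2.71-fold (log2 1.44, SE 0.344, adjusted p = 0.0231, n = 14 against 16), and Syp rose 2.12-fold (log2 1.08, SE 0.292, adjusted p = 0.0297). Palld, which encodes an actin-bundling protein of motile and contractile cells, fell by 1.05 on the log2 scale (SE 0.284, adjusted p = 0.0298), and Cavin1, needed for caveolae, fell by 1.02 (SE 0.275, adjusted p = 0.0297). The calls numbered 1359 probes, 750 higher and 609 lower, in 839 genes (547 higher and 292 lower), with a median absolute log2 difference of 0.43. Median scaling gave 1254, of which 831 were higher and 423 lower. The largest rises also included Caln1 (1.20), the neuronal transcription factor Neurod2 (1.14), Camkv (1.12), the neuronal elongation factor Eef1a2 (1.11), Dmtn (1.08), Rasgrf1 (1.03), Kifc2 (0.98) and Chl1 (0.98). The largest falls included Arhgap22 (-1.04, detected on 6 of 14 protective arrays), Dnajb12 (-0.93), the protease Ctsh (-0.90), the histamine-forming enzyme Hdc (-0.89), Cfap206 (-0.94), Ppp1r32 (-0.93), Cfap299 (-0.91) and Morn5 (-0.87). None of these 20 genes passed once chip was a block: 0 of 20 kept the call, with adjusted p of 0.0511 to 0.134, and 0 of 20 passed with position as a covariate (0.251 to 0.525). Without the detection filter 0 of 20 passed as well (0.0534 to 0.114).

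Of 19 general neuron markers 7 were called higher in the protective class, 17 over the list alone, and 19 of 19 had positive differences (median 0.60, adjusted p = 5.3e-08, but 0.571 with an estimated correlation). Elavl3 (0.76) and the microtubule protein gene Mapt (0.81) were among them. With the 4 antagonists left out, the median was 0.29 for neuron markers (adjusted p = 0.000675), 0.285 for synapse genes (0.000208) and -0.41 for cell division genes (6.8e-06), while glutamate receptor genes, excitatory and inhibitory markers did not pass (0.075 to 0.176). That removal was run with the preset correlation only. Synapse genes had 12 of 24 called higher, 18 over the list alone (median 0.49, adjusted p = 3.76e-09, and 0.571 with an estimated correlation), including Syn2 (0.91). Glutamate receptor genes (median 0.38, adjusted p = 0.00245, 2 called, Grik1 at 0.65 and Grik5 at 0.33), excitatory markers (median 0.33, adjusted p = 0.00508, 3 called) and inhibitory markers (median 0.48, adjusted p = 0.044, 2 called) were higher as well, each with 0.571 under an estimated correlation. Cell division genes were lower, with 0 called over all probes and 16 of 18 over the list alone (median -0.53, adjusted p = 4.84e-07, and 0.571 with an estimated correlation). Interferon-stimulated genes had 3 of 18 called lower, 6 over the list alone (median -0.24, adjusted p = 0.000104, and 0.571 with an estimated correlation): Bst2 (-0.52), Psmb8 (-0.45) and Ifi35 (-0.36). Inflammatory genes were lower with 0 called, 4 over the list alone (median -0.22, adjusted p = 0.002, and 0.571 with an estimated correlation), and ribosomal protein genes had 3 of 47 called higher, 8 over the list alone (median 0.06, adjusted p = 0.0451, and 0.571 with an estimated correlation).

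Within chips, neuron markers were higher in the protective class on 6 of 7 chips (mean log2 -0.23 to 1.58), synapse genes on 6 of 7 (-0.28 to 1.48), and cell division genes were lower on 5 of 7 (-1.20 to 0.35). With chip as a block the adjusted p was 7.58e-07 for neuron markers, 3.27e-07 for synapse genes, 5.91e-05 for cell division genes, 0.00157 for interferon-stimulated genes and 0.0848 for inhibitory markers. These p too rest on the preset correlation only. The count depended on single arrays: it was 233 without ifenprodil, 245 without MK-801, 326 without necrostatin-1, 347 without riluzole, 354 without agmatine, 380 without vehicle control 4, 396 without carbenoxolone, 414 without mock control 1, 622 without resveratrol, 668 without mock control 4, 680 without vehicle control 5, 768 without mock control 3, 777 without flecainide, 792 without liothyronine and 836 without mock control 5, and it was 2135 without moxalactam, 2213 without vehicle control 1, 2227 without indomethacin, 2549 without methotrexate and 2718 without 4-PPBP. Controls sit at the first position of every chip, and with position as a covariate limma called 0 probes, with 2824 at an unadjusted p under 0.05 and a smallest adjusted p of 0.251.

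**Figure D2:**
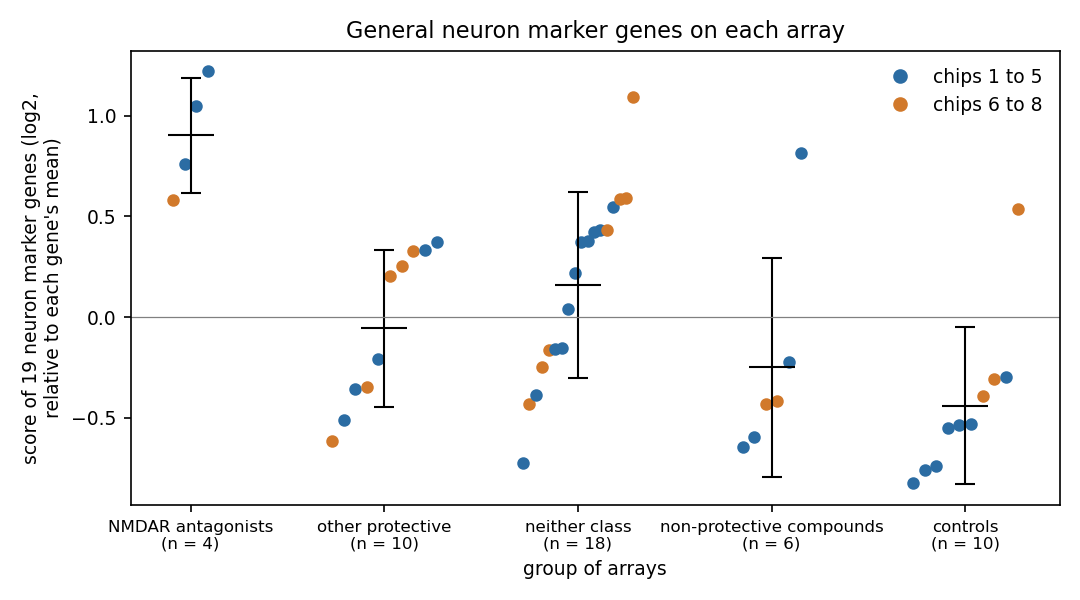
Score of the general neuron markers on each array, in log2 units relative to the mean of all arrays, by group, with the group mean and SD and colours for chips 1 to 5 and 6 to 8. The NMDA receptor antagonists had a mean of 0.90 ± 0.286 SD (n = 4) and the controls -0.44 ± 0.39 SD (n = 10).

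Against the controls alone, Syn2 and Syp were among the genes higher with the protective compounds. Syn2, a synapsin that tethers vesicles, was 2.19-fold higher (log2 1.13, SE 0.234, adjusted p = 0.0113, n = 14 against 10), and Syp was 2.35-fold higher (log2 1.23, SE 0.331, adjusted p = 0.0328). Arhgap22, a regulator of Rac and of cell shape, fell by 1.18 on the log2 scale (SE 0.362, adjusted p = 0.0485, detected on 6 of 14 protective arrays), and Tekt1 (-0.97), Cfap45 (-0.96), Cfap206 (-1.02), Morn5 (-1.05) and Ppp1r32 (-1.02) were lower. The calls numbered 1012 probes, 595 higher and 417 lower, in 608 genes, and 956 with median scaling, of which 697 were higher and 259 lower. The count was 529 with chip as a block and 57 with position as a covariate, 52 higher and 5 lower, of which 36 were also called without it. With the 4 antagonists left out it was 14, and none of the 20 genes named here passed (adjusted p of 0.122 to 0.298). Sncb (1.56), the ubiquitin-activating enzyme Uba6 (1.29), Neurod2 (1.28), Eef1a2 (1.20), Kifc2 (1.12), C2cd4c (1.10, detected on 2 of 10 controls), Rasgrf1 (1.09) and Syn1 (1.09) had the other large rises, and Palld (-1.08), Cavin1 (-1.08), Hdc (-1.04) and Plekha7 (-0.98, detected on 4 of 14 protective arrays) the other large falls. Of these 20 genes, Syn2 and Uba6 kept the call with chip as a block and 18 lost it, Syp among them (adjusted p up to 0.141), and 20 lost it with position as a covariate (0.0615 to 0.341). Without the detection filter 19 of the 20 lost it (adjusted p up to 0.12).

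The 10 other protective compounds alone had medians of 0.36 for neuron markers (adjusted p = 6.8e-05), 0.36 for synapse genes (2.65e-06) and -0.56 for cell division genes (2.54e-07) against the controls. These p come from camera with the preset correlation, and an estimated correlation was not run on this subset. With all 14, neuron markers had 4 of 19 called higher, 18 over the list alone (median 0.69, adjusted p = 2.48e-08, and 0.434 with an estimated correlation), and synapse genes 8 of 24, 21 over the list alone (median 0.59, adjusted p = 2.98e-10, and 0.434 with an estimated correlation). Glutamate receptor genes (median 0.43, adjusted p = 0.000234), excitatory markers (0.40, adjusted p = 0.004) and inhibitory markers (0.52, adjusted p = 0.0362) were higher, with 0.434 under an estimated correlation. Cell division genes were lower, with 0 called and 16 of 18 over the list alone (median -0.68, adjusted p = 4.39e-08, and 0.434 with an estimated correlation). Interferon-stimulated genes (-0.26, adjusted p = 0.00103), inflammatory genes (-0.25, adjusted p = 0.0035), folate cycle genes (-0.21, adjusted p = 0.0224) and proteasome genes (-0.10, adjusted p = 0.0165) were lower, also with 0.434 under an estimated correlation. Within chips, neuron markers were higher on 6 of 7 (mean log2 -0.72 to 1.52), cell division genes lower on 6 of 7 (-1.20 to 0.17) and folate cycle genes lower on 7 of 7 (-0.51 to -0.04). A fit with chip as a block gave an adjusted p of 1.21e-06 for neuron markers, 1.93e-05 for cell division genes, 0.0113 for folate cycle genes and 0.101 for inhibitory markers, with the preset correlation only. The count was 129 without vehicle control 4, 172 without mock control 1, 248 without vehicle control 5, 260 without ifenprodil, 277 without mock control 4, 354 without MK-801, 377 without carbenoxolone, 389 without riluzole, 407 without mock control 5, 483 without liothyronine, 484 without necrostatin-1, 491 without vehicle control 3, 567 without resveratrol and 586 without mock control 3, and it was 1951 without moxalactam, 2092 without indomethacin, 2302 without methotrexate and 2626 without vehicle control 1.

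Set against the 6 non-protective compounds rather than controls, the 14 protective compounds had no gene past the threshold. The smallest p belonged to Cd44, a hyaluronan receptor of glial precursors and reactive glia, whose mean was lower with the protective compounds (log2 -1.04, SE 0.206, p = 1.84e-05, adjusted p = 0.164 by limma, n = 14 against 6) but did not pass. Zfp398 (0.54), Setd1b (0.46), Tmem141 (-0.58) and Ibtk (0.42) followed, with adjusted p of 0.193 to 0.204. limma called 0 of 17815 probes, with 2435 at an unadjusted p under 0.05. By lists, neuron markers (median 0.41, 19 of 19 positive, adjusted p = 6.49e-05) and synapse genes (0.40, 24 of 24 positive, adjusted p = 6.49e-05) were higher, as were ribosomal protein genes (0.11, adjusted p = 0.00324), each with 0.762 under an estimated correlation. Cell division genes (-0.35, adjusted p = 0.00209, and 0.795 with an estimated correlation), interferon-stimulated genes (-0.20, adjusted p = 6.49e-05, and 0.762) and inflammatory genes (-0.20, adjusted p = 0.00745, and 0.762) were lower. Leaving out the 4 antagonists gave an adjusted p of 0.167 for neuron markers (median 0.215) and 0.227 for synapse genes, while cell division genes (0.045), interferon-stimulated genes (0.00185) and ribosomal protein genes (0.00185) passed. Leaving out 4-PPBP, a non-protective compound with high neuron markers, gave a median of 0.72 for neuron markers (adjusted p = 1.39e-07). Both removals were run with the preset correlation only. Over the list alone 1 neuron marker passed as higher and 2 interferon-stimulated genes as lower. On the 4 chips with compounds of both kinds, neuron markers were higher on 3 (mean log2 -0.41 to 1.63), cell division genes lower on 3 (-1.50 to 0.87) and ribosomal protein genes higher on 4 (0.04 to 0.17), and with chip as a block the adjusted p was 0.000249 for neuron markers and 0.0157 for cell division genes. Without cyclophosphamide limma called 2 probes.

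Few probes separated the non-protective compounds from controls. limma called 3 probes, 0 of them higher and 3 lower, and none carries a gene symbol, while 1106 had an unadjusted p under 0.05. The smallest p of a named gene belonged to the cyclin Ccni (log2 0.65, SE 0.144, adjusted p = 0.241, n = 6 against 10, detected on 3 of 10 controls), followed by the energy sensor subunit Prkaa2 (0.42, detected on 1 of 10 controls and 3 of 6 compounds), the peptidase Anpep (1.06), the mitochondrial enzyme Tst (0.46) and Tomm6 (0.67), with adjusted p up to 0.346; none passed. Glutamate receptor genes (median 0.28, adjusted p = 0.00221), synapse genes (0.18, adjusted p = 0.00221), neuron markers (0.17, adjusted p = 0.0215), SREBP2 targets (0.16, adjusted p = 0.0215) and lysosome genes (0.13, adjusted p = 0.00553) were higher by camera. Cell division genes (-0.37, adjusted p = 0.00221), folate cycle genes (-0.18, adjusted p = 0.0432) and proteasome genes (-0.12, adjusted p = 0.00553) were lower, and with an estimated correlation the adjusted p was 0.575 for lysosome genes and 0.929 for the other 7 lists. These calls depended on 4-PPBP, with a neuron marker score of 0.816 against -0.645 to -0.223 on the other 5 arrays. Without it 0 of the 8 lists passed (adjusted p of 0.0801 to 0.949), and the medians were -0.01 for neuron markers, 0.04 for synapse genes and -0.06 for cell division genes. Proteasome genes alone had an adjusted p under 0.05 with chip as a block (0.00189), neuron markers had 0.338, and within chips neuron markers were higher on 2 of 5 (mean log2 -0.97 to 1.11) and proteasome genes lower on 4 of 5. The count was 11 without agmatine and 1 without each of citicoline, baclofen, mock control 2, mock control 4 and mock control 5.

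Over all 36 compounds, expression was also set against the measured protection. No gene passed: the smallest p belonged to the microtubule organiser gene Mzt1 (log2 0.47 per doubling of the ratio, SE 0.121, adjusted p = 0.847), followed by Nudt11, Nkap, Lrrc20 and 4930402H24Rik at the same adjusted p. limma called 0 probes, with 951 at an unadjusted p under 0.05. Neuron markers (median slope 0.31, adjusted p = 0.000308), synapse genes (0.29, adjusted p = 0.000127), excitatory markers (0.20, adjusted p = 0.0333) and ribosomal protein genes (0.06, adjusted p = 0.0286) had higher values with a larger ratio by camera. Cell division genes (-0.24, adjusted p = 0.000901), interferon-stimulated genes (-0.22, adjusted p = 0.000346) and inflammatory genes (-0.22, adjusted p = 0.00129) had lower ones, and each of the 7 lists had 0.819 with an estimated correlation. With chip as a block the adjusted p was 0.0283 for neuron markers, 0.0696 for synapse genes, 0.404 for inflammatory genes and 0.00453 for cell division, interferon-stimulated and ribosomal protein genes.

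As a correlation across the 36 compounds, the neuron marker score had a Pearson r of 0.20 with the ratio (permutation p = 0.243, adjusted p = 0.828 over 34 lists) and a Spearman rho of 0.21 (permutation p = 0.209, adjusted p = 0.752). Without rolipram and benzamide, whose ratios of 2.76 and 2.01 lie farthest from the median, r was 0.28 (permutation p = 0.112, n = 34). It was 0.29 on chips 1 to 5 (permutation p = 0.198, n = 22) and -0.04 on chips 6 to 8 (permutation p = 0.901, n = 14). Over all 36 compounds the number of lists with a permutation p under 0.05 for Pearson's r was 0 of 34. Without rolipram and benzamide it was 1, excitatory neuron markers (r = 0.35, permutation p = 0.0456, not adjusted over the lists).

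**Figure D3:**
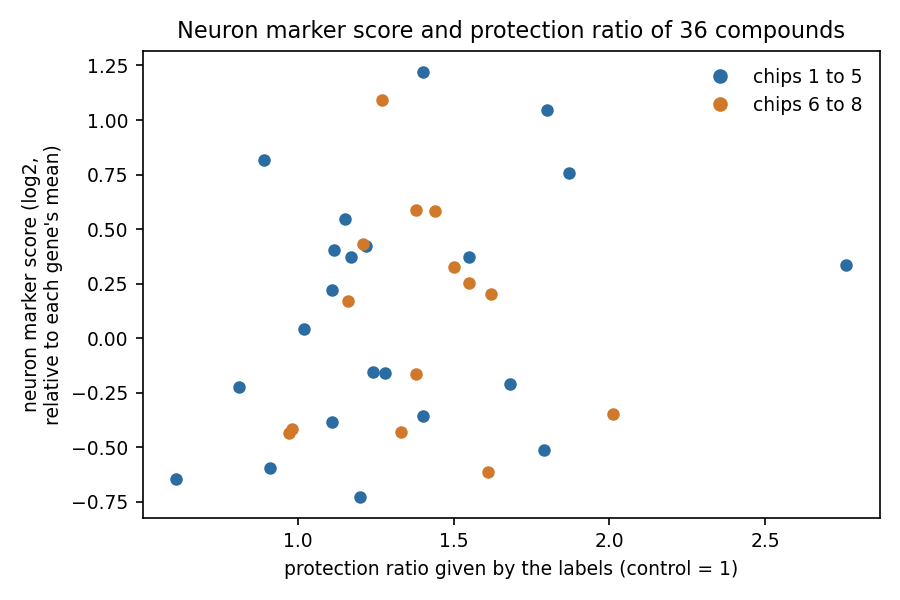
Protection ratio of each of the 36 compounds (x axis) against its score of general neuron markers in log2 units (y axis), coloured by chip set. Pearson's r was 0.20 (permutation p = 0.243).

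Vehicle controls, which received DMSO, and mock controls, which received water, were compared as 5 against 5. The AMPA receptor subunit gene Gria3 had a lower mean in vehicle controls (log2 -1.02, SE 0.164, adjusted p = 0.117 by limma, n = 5 against 5), as had Zfp445 (-1.11), Zc3h18 (-0.62), Pcmtd1 (-0.78) and Sltm (-0.75), and none passed. limma called 0 probes, with 3554 at an unadjusted p under 0.05. With chip as a block, which leaves 1 residual degree of freedom, it called 4378 probes, and these 5 genes passed with the same direction (adjusted p of 0.000511 to 0.0103). That fit rests on chips 1 and 2, where the vehicle controls lie at position B and the mock controls at position A. It therefore cannot tell the solvent from position on the chip. Microglia markers, which read out resident immune cells, were lower in vehicle controls by camera (median -0.29, 0 of 11 positive, adjusted p = 0.0142, and 0.902 with an estimated correlation), and so were astrocyte markers (median -0.16, adjusted p = 0.0153, and 0.902 with an estimated correlation). Chips 1 and 2 are the only ones with controls of both kinds, and there the microglia markers were higher in the vehicle control on 2 of 2 (0.28 and 0.33). With chip as a block the microglia markers were higher in vehicle controls too (camera adjusted p = 0.0234). Both values share the overlap of solvent and position. The astrocyte markers then had an adjusted p of 0.17. The count was 780 without vehicle control 5 and 12 without mock control 4.

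Labelled mechanisms with at least 3 compounds were compared in one test over 29 samples. The labels were used as given, although propranolol and mifepristone, labelled receptor agonist, are known as receptor antagonists. limma's moderated F test called 0 probes, with 808 at an unadjusted p under 0.05 and a smallest adjusted p of 1; without nimodipine it called 1.

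Single compounds were described against the 10 controls without a test, since each has 1 array. Simvastatin, which blocks the rate-limiting enzyme of cholesterol synthesis, had all 18 of 18 SREBP2 target genes above the control mean (median log2 1.00, against -0.18 to 0.51 for a control array set against the other 9), led by Mvd (2.23), Lss (1.68) and Fdps (1.65). It ranked 1 of 36 compounds and stayed at 0.75 after chip means were subtracted. Both interferons had high interferon-stimulated genes. Interferon-a2b had a median of 1.51 with 18 of 18 genes higher, led by Oasl2 (3.04, detected on 3 of 10 controls), Rsad2 (2.39) and Ifit3 (2.23), and interferon-b1a had 0.92 with 18 of 18 higher, against -0.36 to 0.26 among controls. With chip means subtracted they were at 1.31 and 0.80. These 3 medians lay at the percentile of 100 among random lists of like expression.

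Immediate early and activity-regulated genes, which neurons switch on when calcium enters, were low with the receptor blockers. MK-801 had a median of -0.59 and memantine -0.37, both below the control range of -0.10 to 0.20, and -0.39 and -0.34 after chip means were subtracted, again outside the controls. Ifenprodil (-0.45), the calcium channel blocker nimodipine (-0.29) and riluzole (-0.12) were below the range too, but inside it once chip means were subtracted (-0.22, -0.21 and -0.04). Each chip mean includes the compound's own array, and MK-801 and riluzole share chip 4. Subtraction thus removes part of a fall, also of a shared one. FK-506 (0.08) and baclofen (0.04) were inside it. Ranked from the highest of 36 compounds, MK-801 was 36, ifenprodil 34, memantine 33, nimodipine 32 and riluzole 26, so other compounds also had low values. Minocycline had inflammatory genes at 0.65 with 11 of 16 higher, above the control range of -0.46 to 0.34, and ranked 1 of 36. After chip means were subtracted the median was 0.35 and ranked 2 of 36.

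Methotrexate had p53 targets at 0.20 and indomethacin PPARalpha targets at -0.22, both outside the controls, and both inside them with chip means subtracted (0.05 and -0.21). Clofibric acid, a PPARalpha agonist, had that list at 0.26, outside the controls, and at -0.05 with chip means subtracted. Thyroid hormone targets were at 0.56 with liothyronine, the hormone T3, inside the control range, which reached 1.02, although Klf9, a known target, was 1.84 above the control mean. Inside the control range were also glucocorticoid targets with mifepristone (-0.23) and carbenoxolone (-0.16), cAMP-CREB targets with rolipram (-0.01) and propranolol (-0.08), p53 targets with cyclophosphamide (0.01) and azathioprine (-0.08), and folate cycle genes with methotrexate (-0.04). Resveratrol had aryl hydrocarbon receptor targets at -0.21 and Nrf2 targets at 0.24, ethyl ferulate Nrf2 targets at -0.11 and heat shock genes at -0.12, indomethacin inflammatory genes at -0.09, erythropoietin hypoxia genes at 0.09 and Z-VAD-FMK apoptosis regulators at -0.01, all inside it. After chip means were subtracted, Nrf2 targets with resveratrol (0.22), heat shock genes with ethyl ferulate (-0.13) and hypoxia genes with erythropoietin (0.12) lay just outside it.

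**Figure D4:**
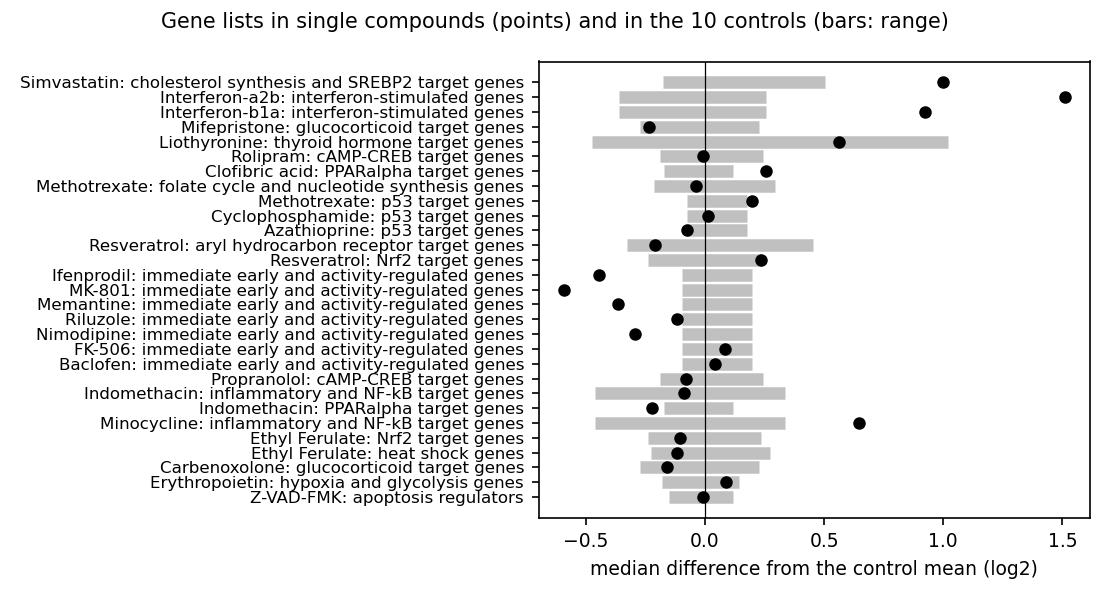
Median log2 difference from the control mean of the list assigned to each compound, with the range of the 10 control arrays, each set against the other 9, as a bar. Interferon-a2b (1.51), simvastatin (1.00) and interferon-b1a (0.92) lie farthest above their control ranges.

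The arrays as a whole separated first by chip. The first principal component held 30.1% of the variance, of which membership of chips 1 to 5 or 6 to 8 took 70.9%, group 18.6% and solvent 13.9%. Its mean was -19.6 ± 18.1 SD on chips 1 to 5 and 32.6 ± 13.5 SD on chips 6 to 8. The second component held 23.4%. The neuron marker score of controls differed between these sets too: -0.61 ± 0.182 SD on chips 1 to 5 (n = 7) and -0.05 ± 0.515 SD on chips 6 to 8 (n = 3).

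**Figure D5:**
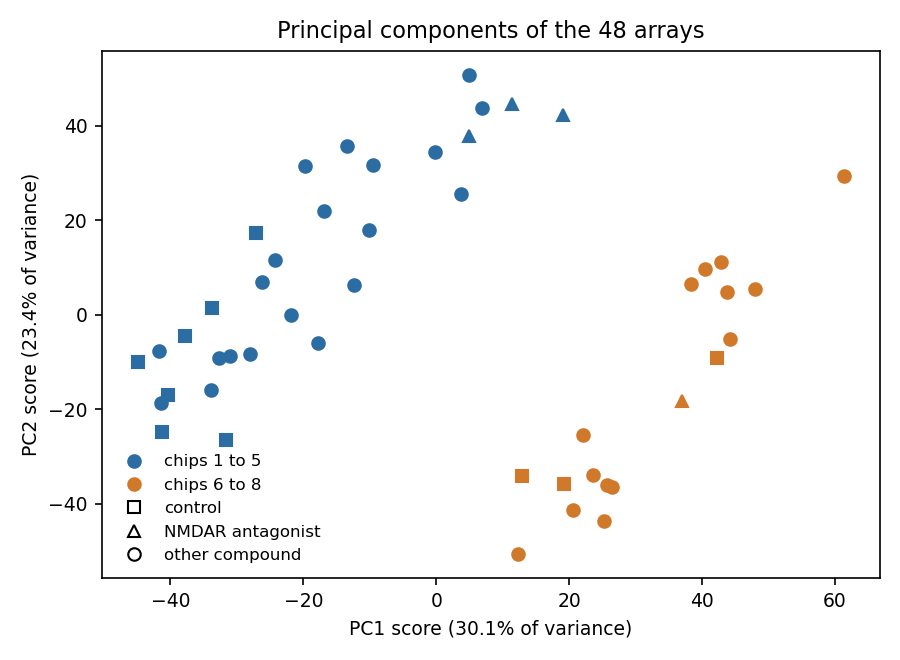
Scores of the 48 arrays on the first (30.1% of variance) and second (23.4%) principal components of the log2 intensities, marked by group and chip set. Chips 1 to 5 had a mean first score of -19.6 and chips 6 to 8 of 32.6.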

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

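The tests of the antagonist pattern and its explanations were chosen only after the result was seen. Arrays that stood apart from their group by Dixon's criterion were sought in 110 groups of list scores, of which 7 had one, and in 114 groups of gene values, of which 18 had one; chance gives about 1 in 20 groups.

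Vehicle control 1, on chip 6, stood apart from the other controls as the highest array for 15 of the genes that the comparisons name. Its log2 values were 10.1 for Syn1, 6.56 for C2cd4c, 7.75 for Kifc2, 9.35 for Syn2, 9.81 for Eef1a2, 10.2 for Syp, 8.25 for Neurod2 and 8.23 for Sncb. They were 7.69 for Lin7b, 8.16 for Cck, 7.71 for Chl1, 9.11 for Camkv, 7.94 for Myh8, 8.46 for Lrfn5 and 8.31 for Stum. These genes go together on the arrays and are not 15 independent observations. Its scores of 0.589 for excitatory neuron markers and 0.155 for calcium and potassium homeostasis genes were also the highest of the 5 vehicle controls. Without this array the class contrast called 2213 probes.

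Among the 6 non-protective compounds, 4-PPBP had the highest score for general neuron markers (0.816, with the next at -0.223) and for calcium and potassium homeostasis genes (0.258, with the next at -0.0505). Mock control 2 was the lowest control for Morn5 (8.77) and Tekt1 (8.73), and mock control 4 the lowest mock control for PPARalpha targets (-0.0318). Among the 4 NMDA receptor antagonists, memantine had the highest score for interferon-stimulated genes (0.0124, the others at -0.446 to -0.396) and the highest Tk1 value (8.63, the others at 7.08 to 7.29). Riluzole had the lowest score for cholesterol synthesis and SREBP2 target genes (-0.169, the others at 0.323 to 0.389). 4-PPBP was given in ethanol, a solvent without control arrays. No explanation of these single arrays was tested.

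The effects of NMDA receptor antagonists and of other protective compounds against the controls differed at 1024 probes, by a direct test of the difference. Of 100 splits of these arrays, the real one included, 6 called as many probes, with up to 2341 in another split, so chance cannot be excluded for this count. The split with 2341 had a correlation of 0.0913 with the chip sets, and what it follows was not tested. The same splits called as many gene lists as the real one, 17, in 1 case, with up to 14 in another split, a share under 0.05, though 0 lists passed in the real split with an estimated correlation.

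The neuron marker and synapse genes that were higher on the 4 antagonist arrays were weighed as a pattern, over 39 genes with a mean difference of 1.22 from the controls. Differences between chips are argued against, since with chip as a term the difference was 1.18 (SE 0.157, 95% interval 0.781 to 1.59) and was present on 3 of 3 chips. Among compound arrays, a straight-line effect of position is argued against as the whole cause. With chip and position as terms, the difference of the antagonists from the other compounds was 0.779 (SE 0.261, 95% interval 0.244 to 1.31). Antagonists lie at positions D to F and controls at A and B, and the controls were left out. Position thus stays open for the difference from the controls. A larger share of neurons, from better survival or fewer other cells, may account for the pattern. Better survival, as far as the protection ratio measures it, is argued against as the whole cause. The 4 antagonists had neuron marker scores of 0.583 to 1.22 at ratios of 1.4 to 1.87. The other protective compounds had scores of only -0.613 to 0.371 at ratios of 1.4 to 2.76. The assay behind the ratio is not given, so survival that it does not measure stays open. A larger share from fewer other cells stays open too. The markers of the 4 other cell classes moved apart by 0.415 at most (SE 0.391, 95% interval -0.436 to 1.27). Their differences were -0.228 for astrocytes, -0.186 for oligodendrocytes, -0.394 for microglia and -0.601 for vessel cells. A change of transcription within neurons cannot be told apart from such a share with these values.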

How the results depend on the processing

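The alternatives with chip set, position, subsets of chips, arrays that stood apart, or without 4-PPBP or the 4 antagonists together were chosen after seeing the data, and the others were planned. For all values below the cause was not tested, except where fewer arrays or probes are named.

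Counts of probes called depended on the settings as follows. For the class contrast (1359) no filter gave 249, over more probes, chip as a block 406, of which 303 were also called without it, array weights 5503, chip set as a block 2232, position as a covariate 0, and with fewer arrays chips 6 to 8 only 0 and no antagonists 0. Leaving out 1 array gave 233 to 2718. Protective against non-protective compounds (0) gave 2758 with array weights and 0 to 2 without 1 array. Protective compounds against controls (1012) gave 220 without a filter, 529 with chip as a block, of which 381 were also called without it, 5275 with array weights, 1919 with chip set, 57 with position, 1551 on chips 1 to 5, 1 on chips 6 to 8, 14 without the 4 antagonists, and 129 to 2626 without 1 array. Non-protective compounds against controls (3) gave 1 with median scaling, 6 with chip, 525 with array weights, 9 with chip set, 0 on chips 1 to 5 and 1 on chips 6 to 8, and 1 to 11 without 1 array. Controls lie at positions A and B, so position and group are partly the same. The 4 antagonists lie at positions D to F, apart from every control.

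The slope on the protection ratio had 0 calls under each alternative, and 0 without each of the 38 arrays in turn, which keeps MitoPBN and Z-VAD-FMK in the fit through their other array. Vehicle against mock controls (0) gave 4378 with chip as a block, which leaves 1 residual degree of freedom within chips, 3539 with array weights, 51 on chips 1 and 2 only, 4297 with position, and 0 to 780 without 1 array. On chips 1 and 2 solvent cannot be told apart from position. With position as a covariate, vehicle controls of chips 6 to 8 were set against mock controls of chips 1 to 5, so solvent cannot be told apart from chip set. The replicate block gave 0 with a smallest adjusted p of 0.252; controls of like number correlated at -0.141 to 0.146, with 1 of 5 over 0.1 and 0 of 5 best with their own number, so the numbers do not pair them. NMDA receptor antagonists against controls (3445) gave 7370 with array weights, 5310 with chip set, 1371 with position, 6705 on chips 1 to 5, 0 on chips 6 to 8, where there is 1 antagonist, assumed to vary like the other groups, and 1665 to 4104 without 1 array. Against other protective compounds (1024) array weights gave 2680, solvent as a covariate 625, chip set 2234, chips 1 to 5 gave 2561, chips 6 to 8, again with 1 antagonist, gave 0, and 110 to 1471 without 1 array. Among the calls with chip as a block, 2066 and 651 were also called without it. The test of mechanisms (0) gave 5 with chip, 10181 with array weights, 1 on chips 6 to 8, 2 without the arrays that stand apart, and 0 to 1 without 1 array.

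Counts of gene lists fell to 0 in each comparison with an estimated correlation. With fry 5 lists passed for the class (9), 0 for protective against non-protective compounds (6), 0 for non-protective compounds against controls (8), 0 for the slope (7), 0 for vehicle against mock controls (2) and 21 for antagonists against controls (12). Under chip as a block 1 passed for non-protective compounds against controls, 4 for the slope, 12 for vehicle against mock controls and 19 for antagonists against controls. With chip set 7 passed for vehicle against mock controls, and with position 3 for non-protective compounds against controls. Without 4-PPBP 0 passed for non-protective compounds against controls and 10 for protective against non-protective compounds, which had 3 without the 4 antagonists.

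Without 4-PPBP the direction of neuron markers in non-protective compounds against controls reversed, with an adjusted p of 0.949. The direction of microglia markers in vehicle against mock controls reversed to higher. The camera adjusted p was 0.0234 with chip as a block and 0.0725 with chip set as a block. Both fits set vehicle controls at position B against mock controls at position A, so solvent cannot be told apart from position. The median of PPARalpha targets with clofibric acid reversed to -0.0524 with chip means subtracted. The number of single-compound lists outside the controls (12) was 9 to 13 under the alternatives.

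No named gene that was past the threshold in the main fit or in an alternative changed direction between them. Changes of direction in genes past it in neither were not counted apart. Leaving out 1 array gave 1495 values on the same side of the threshold, 555 no longer past it and 10 newly past it, and the other alternatives 1014, 337 and 25. The direction and call of lists were the same in 458 cases, no longer past the threshold in 153 and reversed in 3. Solvent could not be a covariate for vehicle against mock controls, since it defines the groups, and chips 6 to 8 hold no mock controls. Signal over background sets the depth: 10051 of the 17815 tested probes were detected on all arrays, and the offset of 16 shrinks changes near background.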

Other observations

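The tests of the chip sets and of the switching probes were chosen only after the result was seen, and the counts over splits of the samples were planned.

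Several single arrays of compounds in neither class carried large changes, without a replicate except for MitoPBN. On the clofibric acid array the chemokine gene Ccl4 and the oligodendrocyte transcription factor genes Sox10 and Olig2 were undetected, at least 22.1-fold, 17.9-fold and 10.4-fold below the control mean, and its scores of -2.49 for oligodendrocyte markers and -2.22 for microglia markers were the lowest of the 48 arrays. On the minocycline array the stress genes Trib3 (3.81) and Nupr1 (3.35) were high, with a score of 1.79 for integrated stress response genes, while Ccl9 (-2.40), Gpr17 (-2.24) and Tk1 (-2.18) were low. MitoPBN array 1 also had high Trib3 (2.47) and a stress response score of 1.06, but the array of MitoPBN2, its repeat by title, had a score of 0.341. On the erythropoietin array the antioxidant genes Gsta3 (3.11) and Srxn1 (2.56) were high, with the highest Nrf2 target score of the 48 arrays (0.88). Nimodipine, an L-type calcium channel blocker in neither class, had the highest synapse score (1.15), a neuron marker score of 1.09 and 1412 genes beyond the controls, against 917 for MK-801, 1322 for clofibric acid and 12 to 703 for single controls set against the other 9. Nimodipine and clofibric acid were given in ethanol, which the controls did not receive, so compound and solvent cannot be told apart there.

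Repeat arrays of a compound were compared by their differences from the chip means. The MitoPBN and MitoPBN2 arrays correlated at 0.379 across genes, rank 2 of 20 pairs from the same 2 chips, and the 2 Z-VAD-FMK arrays at -0.185, rank 18 of 25; genes are not independent replicates.

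Each comparison except the slope on the protection ratio was repeated on 100 splits of its samples, the real split included. For probes, 1 split called as many as the class contrast (1359, highest other 30), 2 as many as protective compounds against controls (1012, highest other 2818), 2 as many as non-protective compounds against controls (3, highest other 32) and 1 as many as NMDA receptor antagonists against controls (3445, highest other 2262), so each share was under 0.05. These splits move arrays freely between chips and positions. A share under 0.05 makes a chance draw of arrays unlikely but does not exclude it, and the splits cannot address an effect of chips or of position. Another split called more than the real one for protective compounds and for non-protective compounds against controls, and the count of 3 for the latter was 1 without any of 5 arrays (citicoline, baclofen and mock controls 2, 4 and 5) and 11 without agmatine, so it is not a firm one. The split with 2262 set arrays of 1 chip set against arrays of the other; with chip as a block the real antagonist contrast called 2583, of which 2066 were also called without the block. The split with 2818 followed the chip sets in part (r = 0.742), and the real contrast called 529 with chip as a block. With 0 calls, all 100 splits gave as many for protective against non-protective compounds (highest other 3980), for vehicle against mock controls (highest other 14) and for mechanisms (highest other 7), and the split with 3980 had a correlation of 0.579 to the chip sets. For gene lists, as many were called in 26 splits for the class (9 lists, highest other 15), 55 for protective against non-protective compounds (6, highest other 17), 30 for protective compounds against controls (10, highest other 23), 32 for non-protective compounds against controls (8, highest other 16), 88 for vehicle against mock controls (2, highest other 16) and 23 for antagonists against controls (12, highest other 20). Chance cannot be excluded for these counts of lists.

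Arrays of chips 6 to 8 lay apart from those of chips 1 to 5 on the first component. DMSO in the vehicle controls is argued against, since the 2 vehicle controls of chips 1 and 2 had a mean score of -40.8, on the side of their chips, and those of chips 6 to 8 one of 24.8. More protective compounds on 1 set is argued against, since class took 6.28% of the variance among the classed compound arrays. Labelling or hybridisation of the 2 sets at different times could account for it: the set took 74.8% of the variance among compound arrays in water. This cannot be told apart from separate preparations of cultures, since the labels give neither.

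Among the probes, 11 switched between a high and a low level across arrays with at least 1.5 log2 units between, 9 of them for named genes. Low arrays numbered 4 for Tmem14c (rolipram, interferon-a2b, MK-801 and vehicle control 3), 9 for Tmem68 and 19 for H2-D1. Between the same arrays the other tested probe shifted by only 0.274 for Tmem14c and 0.0166 for H2-D1, so it did not share the switch. The other named switching genes had no other tested probe. The compounds are argued against as the cause for the 5 probes that had control arrays at both levels. For the other 6, Efs, Csrp1, Cops8, Sri, Cldn12 and 1 unnamed probe, no control was at the rarer level, where random sets of arrays give 4.08 such probes, so the compounds stay open for these. A fault of 1 chip is argued against for the 9 that switched on more than 1 chip and stays open for the other 2. On 1 chip alone were Efs, high on 3 arrays of chip 5 (deprenyl, interferon-b1a and moxalactam), and Rnaseh2a. The Cldn12 and Sri probes, on 1 chromosome with 25 genes between, were low on the same 3 arrays (MitoPBN2, azathioprine and simvastatin), which is 1 of 17296 possible sets of 3. Csrp1 and Cops8, the other pair on 1 chromosome, with 572 genes between, shared 0 arrays. Genes on different chromosomes shared arrays too: in 6 of 34 such pairs the smaller set lay wholly within the larger, where random sets give 0.491, with the 4 arrays of Tmem14c within the 9 of Tmem68, and those of Tmem14c, Tmem68, Cops8, Sri and Cldn12 within the 19 of H2-D1. An inherited difference between cultures of outbred mice, such as a variant under the probes, may explain the switching and stays open: 1 pair on 1 chromosome shared the same arrays, but sharing between chromosomes is not what linkage predicts, and the labels do not give the parentage that would decide it.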
